A study of Arabidopsis thaliana with 8 samples.

How the data were processed

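ATAC-seq was performed by the authors on FACS-sorted protoplasts of DRNL::erGFP ap1 cal inflorescence apices, and on sheared DNA as a control, per the labels' protocols. The labels name 8 libraries, 3 of GFP-positive cells, 3 of GFP-negative cells and 2 sheared controls. Site lists were used for the 6 sorted libraries, and the controls were not analysed here. The groups and replicate numbers were taken from the sample titles.

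Per the submitters' processing notes, BWA 0.7, SAMtools 0.1.19, Picard 1.105, bedtools 2.17.0 and SICER were used with the TAIR10 genome. The version of SICER, the role and order of the tools, any read shift for the transposase, the duplicate and organelle filters, the window, gap and threshold of the site calls and the use of the controls are not given in the sources used here. The deposited lists give a chromosome, start, end and score for each THS, with no header and 1 list per library. The score is the authors' own value for each site, on a scale that is not stated, and was used here only to rank and describe sites within a list. All starts were multiples of 100 and all ends finished in 99, so sites were read as whole 100 bp windows that include the last base, and positions are printed counting from 1. The files listed sites on the 5 nuclear chromosomes alone. The read depth per library is not given in the sources used here. The number and total length of sites stand in its place, and a library with more sites can reveal regions that another misses.

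The deposited table of the whole series holds 4 columns of gene identifiers (unit: other, with no numbers): genes with THSs in each population and genes with dTHS-up or dTHS-down sites. The pooling, the rule that assigned sites to genes and the threshold are not given in the sources used here. Of its genes, 25603 of 25995 (GFP-positive), 20799 of 21098 (GFP-negative), 116 of 121 (dTHS-up) and 385 of 392 (dTHS-down) matched a nuclear locus of the reference table. It holds no counts or values, so no test on values was possible.

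Gene names, types and positions came from a RefSeq gene table of assembly TAIR10.1, with 27444 nuclear protein-coding genes. TAIR10.1 keeps the nuclear chromosome sequences of TAIR10. This was checked on the data: of the genes in the authors' GFP-negative list, at least 99.8% per chromosome had a GFP-negative THS within 1000 bp, and at most 78.6% when the genes were shifted by 5000 bp. Positions printed are those of the deposited sites. The table gives no strand and no exons, so gene windows extend 1000 bp to both sides where an upstream window had been planned, and exons, introns and UTRs were not separated. No genome sequence was at hand, so the planned motif test was not run.

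Numbers of sites, covered length and shares of base pairs by annotation class were compared with exact permutation tests, two-sided, over the splits of the 6 libraries. Similarity was the base-pair Jaccard index, with exact permutation of the group labels. All THSs were merged into union regions, and a region counted as present in a library with at least 1 bp of overlap. For genes, the percent of the window covered by THSs was fitted with limma (eBayes with a trend, no block, genes with coverage in at least 2 libraries), and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The 13 gene lists were tested with camera at a preset inter-gene correlation of 0.01, and with Fisher's exact test for overlap with group-only regions and with the dTHS columns. Groups, tests, gene lists, the rule for named genes and alternatives were fixed before the data were examined, except where stated. The plan did not hold the Fisher's exact tests on the dTHS columns or the adjustment of p-values over a list alone. Loci were counted by joining genes within 5000 bp.

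The text names DRNL, AP1 and CAL first. It then names list members whose window holds a group-only region or that pass limma, up to 15 per direction in list order, and the 10 genes per direction with the smallest limma p among those whose groups do not overlap. List members are also named where needed to say how many changed. A planned ranking of sites in the series table could not be applied, since that table has no values.

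The code was tested on simulated data. For the GFP-positive against GFP-negative comparison, all 150 and 250 planted group-only regions among 2900 were found. With noise drawn from the model on 22497 genes, limma recovered 0 of 50 genes changed by 10 percentage points, 18 of 50 changed by 20, 42 of 50 changed by 30 and 44 of 50 changed by 40, with 9 false calls among 113. With real values shuffled within 21886 genes it recovered 5, 19, 26 and 41 of 50, with 59 of 150 calls at genes without added change. A shuffle can restore a gene's real grouping, so some of these 59 calls can be real differences. The adjusted p may be too small for such values, but the shuffles cannot show by how much. Without added change, 20 such shuffles gave 22 to 62 calls, and 93.9% of these calls fell at the 22.7% of genes with identical coverage in a group. In a further shuffle camera called none of 13 lists. Each gene was shuffled by itself, which removes correlation between genes, so this cannot show how camera behaves with correlated genes. In the other splits of the real libraries camera called up to 3 lists.

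Alternatives were a minimum THS width of 400 bp, joined or merged sites over gaps of 200 bp, other overlap rules, flanks of 2000 bp, flanks alone, another coverage filter, scaling by the library mean, no trend, a replicate block, fry (with its mixed test for changes in either direction), an estimated correlation and leaving out each library. Added after the data had been examined were the 24156 top-scoring sites of each library, all nuclear genes of any type, and leaving out a THS of over 200 kb. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.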

Results

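Accessible chromatin was mapped by ATAC-seq, in which a transposase cuts and tags open DNA, in cells sorted from the inflorescence apices of Arabidopsis thaliana. The plants carried the DRNL::erGFP reporter in an ap1 cal double mutant. In this mutant, flowers are replaced by proliferating inflorescence meristems, so that lateral organ founder cells arise in large numbers. GFP-positive protoplasts were the founder cells, marked by the promoter of DORNRÖSCHEN-LIKE (DRNL), and GFP-negative protoplasts were their neighbours in the same apices. Each population was represented by 3 libraries, which the series describes as biological replicates. A further 2 control libraries, made from sheared DNA, were not analysed here. For each of the 6 sorted libraries a list of transposase hypersensitive sites (THSs) was deposited, and for the series a table of gene lists. The lists give no read counts, so the depth of each library is unknown.

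The comparison asked which parts of the genome were open in founder cells and not in their neighbours, and the reverse. The libraries held similar amounts of accessible chromatin. The GFP-positive libraries contained 24156, 26216 and 25623 THSs and the GFP-negative libraries 26001, 26310 and 28757. The means were 25332 ± 1060 and 27023 ± 1510 (SD, n = 3 each; exact permutation p = 0.2, two-sided). These sites covered 18.1 ± 1.28 Mb in founder cells and 18.5 ± 0.849 Mb in their neighbours (SD, n = 3 each; exact permutation p = 0.6), or between 14.5% and 16.4% of the spanned genome in single libraries. The median THS was 500 bp wide in each library. With 3 libraries per group, the smallest two-sided p that such a test allows is 0.1.

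Sites were concentrated beside genes in both populations. The 1000 bp flanks of protein-coding genes held 44.3% ± 0.542 of the covered base pairs in GFP-positive and 44.0% ± 0.0884 in GFP-negative libraries (SD, n = 3 each), against 20.4% of the spanned genome. Bodies of protein-coding genes held 37.2% ± 0.702 and 37.6% ± 0.0559, against 54.1% of the genome. The shares differed by 0.322 percentage points in flanks (exact permutation p = 0.5) and by -0.33 points in gene bodies (exact permutation p = 0.7), less than the spread of the GFP-positive but more than that of the GFP-negative replicates. Other annotated genes held 1.37% and 1.38%, and 17.1% lay outside these classes in both groups.

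The THS sets of the populations separated. Library pairs from the same population overlapped more than pairs from different populations, with a base-pair Jaccard index (shared length over joint length) of 0.800 ± 0.00801 over 6 pairs within groups and 0.765 ± 0.0106 over 9 pairs between groups (SD). The lowest index within a group, 0.791, lay above the highest between groups, 0.781. The difference of 0.0352 gave an exact permutation p of 0.1, the smallest that 10 splits allow, and the highest of the other splits reached 0.0086.

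**Figure D1:**
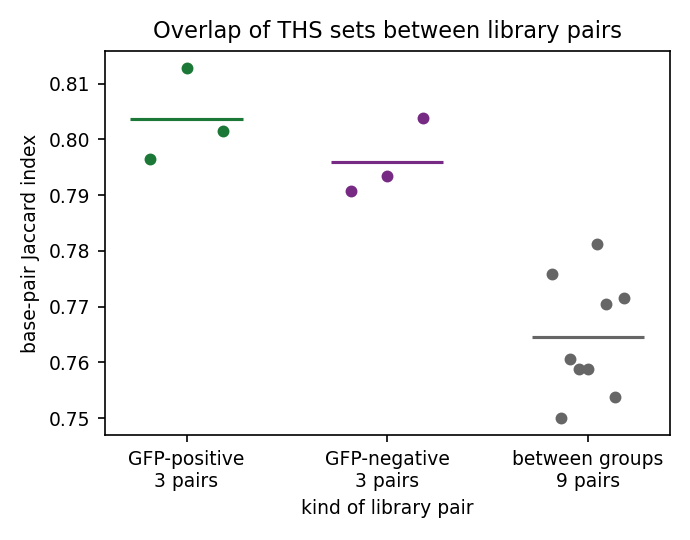
Base-pair Jaccard index (y axis) of each pair of libraries, for the 3 GFP-positive pairs, the 3 GFP-negative pairs and the 9 pairs between the groups (x axis); points are pairs and lines are means. All pairs within a group lie above 0.790, and all pairs between groups lie below 0.782.

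Most accessible regions were shared by founder cells and their neighbours. Joining the 6 lists gave 26792 regions over 23.7 Mb, of which 18768 (70.1%) had a THS in all 6 libraries. That count needs only 1 bp of overlap, and by base pairs 13.6 Mb (57.3%) was covered in all 6 libraries. A set of 112 regions had a THS in all 3 GFP-positive and no GFP-negative library, and 562 had one in all 3 GFP-negative and no GFP-positive library. Of these, 81 and 422 lay within 1000 bp of a protein-coding gene, and 44 and 292 overlapped a gene body by at least 1 bp. Regions said below to lie in a gene or its body overlap it in this sense. Both sets had a median width of 500 bp, against 800 bp for the regions in all 6 libraries.

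Of the 105 protein-coding genes at founder-cell regions, 5 belonged to the gene lists chosen beforehand, and none of these to the founder and organ initiation list (coordinates on TAIR10). A 600 bp region on chromosome 1, from 25983301 to 25983900, lay in the body of AP1 (AT1G69120), the MADS-box gene of floral meristem and sepal identity that is mutated in this line. A 600 bp region on chromosome 5, from 21902601 to 21903200, lay in the body of CUC2 (AT5G53950), a NAC gene that sets organ boundaries. Regions of 300 bp lay in the bodies of AP2 (AT4G36920; chromosome 4, 17401501 to 17401800), a floral organ identity gene, and LAX2 (AT2G21050; chromosome 2, 9033901 to 9034200), which encodes an auxin influx carrier. A further 300 bp region lay within 1000 bp of FDH (AT2G26250; chromosome 2, 11174001 to 11174300), which acts in epidermal wax and cutin formation. None of the 5 genes passed limma on coverage over all genes, with adjusted p from 0.0621 (FDH) to 0.596 (AP2). Mixed sets of 3 libraries shared up to 231 regions of their own, more than the 112 of the GFP-positive libraries.

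Among the regions of the GFP-negative cells, one of 1000 bp lay in the body of the auxin synthesis gene YUC6 (AT5G25620; chromosome 5, 8934701 to 8935700), and one of 800 bp in that of the MADS-box gene FUL (AT5G60910; chromosome 5, 24502301 to 24503100). A region of 600 bp lay in RBCS3B (AT5G38410; chromosome 5, 15376701 to 15377300), which encodes a small subunit of Rubisco. ARR4 of the cytokinin response and the MYB gene RAX2 had such a region within 1000 bp, though their coverage as a whole did not separate the groups. No list of genes held more of these regions than its share by Fisher's exact test after Benjamini-Hochberg adjustment (26 tests). The smallest adjusted p was 0.165, for floral identity genes with a founder-cell region (2 of 25, AP1 and AP2, 0.120 expected).

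The balance between the directions changed with the sites and libraries used. With the 24156 top-scoring sites of each library, a setting chosen after the data had been examined, the counts were 305 founder-cell and 422 GFP-negative regions. Without GFP-negative replicate 3, the library with the most sites, they were 354 and 619. The founder-cell count was 260 without GFP-positive replicate 1 and 183 without GFP-positive replicate 3, and the GFP-negative count was 914 without GFP-positive replicate 2 and 1052 without GFP-negative replicate 1.

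**Figure D2:**
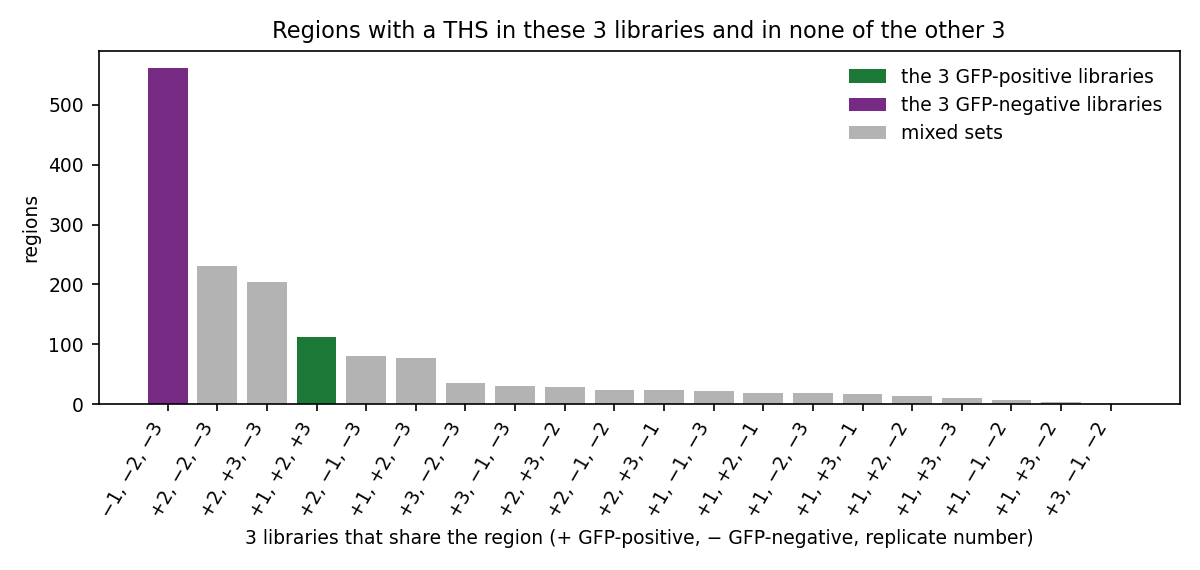
Number of regions (y axis) with a THS in each set of 3 libraries named on the x axis and in none of the other 3. The 562 regions of the GFP-negative libraries exceed all mixed sets, while the 112 regions of the GFP-positive libraries are fewer than those of 2 mixed sets, which have 231 and 204.

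The reporter gene and both mutated genes had higher mean THS coverage in founder cells. For each protein-coding gene, the share of its window (the gene and 1000 bp on each side) covered by THSs was measured. At DRNL (AT1G24590), the AP2-type transcription factor gene whose promoter drives the reporter, coverage was 60.5% ± 5.72 in GFP-positive and 34.7% ± 5.07 in GFP-negative libraries (SD, n = 3 each). At CAL (AT1G26310), which acts redundantly with AP1, it was 69.8% ± 6.38 and 39.2% ± 7.09, and at AP1 41.3% ± 7.05 and 23.4% ± 1.27. All 3 GFP-positive libraries lay above all 3 GFP-negative libraries at each of these genes. The limma adjusted p over all genes was 0.0815 for DRNL, 0.095 for CAL and 0.173 for AP1. In the flanks without the gene body the difference was 34.4 percentage points at DRNL, 7.48 at AP1 and 1.47 at CAL. Sequence of the reporter transgene and the native DRNL locus cannot be separated in these lists.

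Across 21886 genes with coverage in at least 2 libraries, 76 genes (67 loci) had higher and 249 genes (212 loci) lower coverage in founder cells (limma, Benjamini-Hochberg adjusted p under 0.05). The median change was 5.17 percentage points among the higher and -11.2 points among the lower genes. Of the 76 higher genes, 12 had no THS in the window in any GFP-negative library, and 14 held a region seen in the GFP-positive libraries alone. Of the 249 lower genes, 88 had no THS in the window in any GFP-positive library, and 154 held a region seen in the GFP-negative libraries alone. With libraries of the same replicate number taken as a block, only 1 higher and 29 lower genes passed limma. No label says whether a number marks a shared sort.

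Most of the 10 higher genes with the smallest p had identical coverage in all libraries of a group. In shuffled values 93.9% of the calls fell at such genes, so these adjusted p-values may be too small. A shuffle can also restore the real grouping of such a gene, so the extent was not shown. The 10 genes were mostly without a symbol in the reference table. At AT4G09530, listed there also as SAUR17, a small auxin-induced gene, coverage was 15.7% ± 0.38 in founder cells, and no THS was listed in the GFP-negative libraries (SD, n = 3; limma adjusted p = 9.76e-05). MYB66 (AT5G14750), also named WEREWOLF, acts in patterning of the root epidermis. Its coverage was 3.87% in each founder-cell library, with none listed in the others (limma adjusted p = 0.000981). At AT2G17960 coverage was 45.6% ± 2.1 against 15.3% in each GFP-negative library (limma adjusted p = 0.00155). The other 7 were AT5G50365, AT4G32990, AT3G59440, AT5G05050, AT4G35485, AT1G80890 and AT4G32240, with limma adjusted p between 0.000417 and 0.00159. With flanks of 2000 bp, 7 of the 10 no longer passed, and the difference at AT4G35485 was -0.111 points.

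Of the 10 lower genes with the smallest p, 8 had no listed THS in any founder-cell library. All 10 had identical coverage in the libraries of each group, so their adjusted p-values may be too small as well. LBD21 (AT3G11090), of the LATERAL ORGAN BOUNDARIES domain family, was covered over 23.9% of its window in each GFP-negative library (limma adjusted p = 8.81e-05). The transcription factor gene MYB78 (AT5G49620) was covered over 11.4% and the cellulose synthase-like gene CSLB04 (AT2G32540) over 10.2%. The others were AT5G36710, AT5G46010, AT1G09500 and the neighbours AT5G40680 and AT5G40690, whose windows overlap. NUDT8 (AT5G47240), a Nudix hydrolase gene, and AT3G08490 kept some coverage in founder cells, with 7.28% against 26.2% and 5.85% against 25.1%.

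Of the 325 genes, 230 had identical coverage in the 3 libraries of at least 1 group. Values shuffled within genes gave 40.2 calls on average over 20 shuffles, against the 325 found. A shuffle can restore a gene's real grouping, so real differences can be among the 40.2 calls. Their number therefore cannot show how many of the 325 arose by chance. Other splits of the real libraries gave 11 to 50 calls, so part of the 325 may be due to chance. Groups did not overlap at 10.2% of the genes tested, while 3.61% had all founder-cell libraries above and 6.63% all below. Chance gives 10% where no values are tied and less where they are, and ties were frequent here. With the 24156 top-scoring sites per library the calls were 187 higher and 274 lower. Without GFP-negative replicate 3 there were 208 higher genes, without GFP-positive replicate 3 130, and the lower genes were 141 without GFP-positive replicate 1, 158 without GFP-positive replicate 3 and 443 without GFP-negative replicate 1, which gave 540 calls in all.

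Genes of founder cells and organ initiation stood out among the 13 gene lists. Mean coverage of the 19 genes was 43.6% ± 2.99 in GFP-positive and 30.9% ± 2.06 in GFP-negative libraries (SD, n = 3 each), and camera, limma's test of a list against other genes, gave an adjusted p of 7.57e-10. With an estimated inter-gene correlation the adjusted p was 0.199. The list includes DRNL, whose promoter defined the sorted cells, and it was not tested without this gene. Over all genes 1 member rose, AS2, and 8 rose when adjusted over the list alone, an adjustment that was not planned. None fell by either count. AS2 (AT1G65620), which acts in leaf polarity, had the largest change in the list, from 16.3% ± 6.63 in GFP-negative to 58.3% ± 1.19 in GFP-positive libraries (limma adjusted p = 0.0164). Without GFP-positive replicate 1, 2 or 3 its adjusted p was 0.0746, 0.0551 or 0.0652 (limma).

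The other members that rose when adjusted over the list alone were DRNL, PUCHI, LFY, FIL, YAB3, PHV and AHP6. FIL (AT2G45190) and YAB3 (AT4G00180), YABBY genes of abaxial organ identity, had 53.6% ± 11.5 against a value of 21% in each GFP-negative library, and 62.5% ± 3.04 against 49.2% ± 3.97. PUCHI (AT5G18560), an AP2-type gene of floral meristem identity, had 35.3% ± 1.64 against 11.1% ± 10.2. AHP6 (AT1G80100), an inhibitor of cytokinin signalling, had 49.7% ± 5.38 against 34.2% ± 3.11. LFY, the master regulator of floral fate, was widely accessible in both populations, at 89.0% ± 1.22 and 82.7% ± 1.22 (SD, n = 3 each throughout). DRN, the closest relative of DRNL, had 59.5% ± 14.3 and 34.9% ± 17.5 and did not pass, and neither did ANT, AIL6, AIL7, AS1, BOP1, BOP2, PHB, REV, LMI1 and KAN1.

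**Figure D3:**
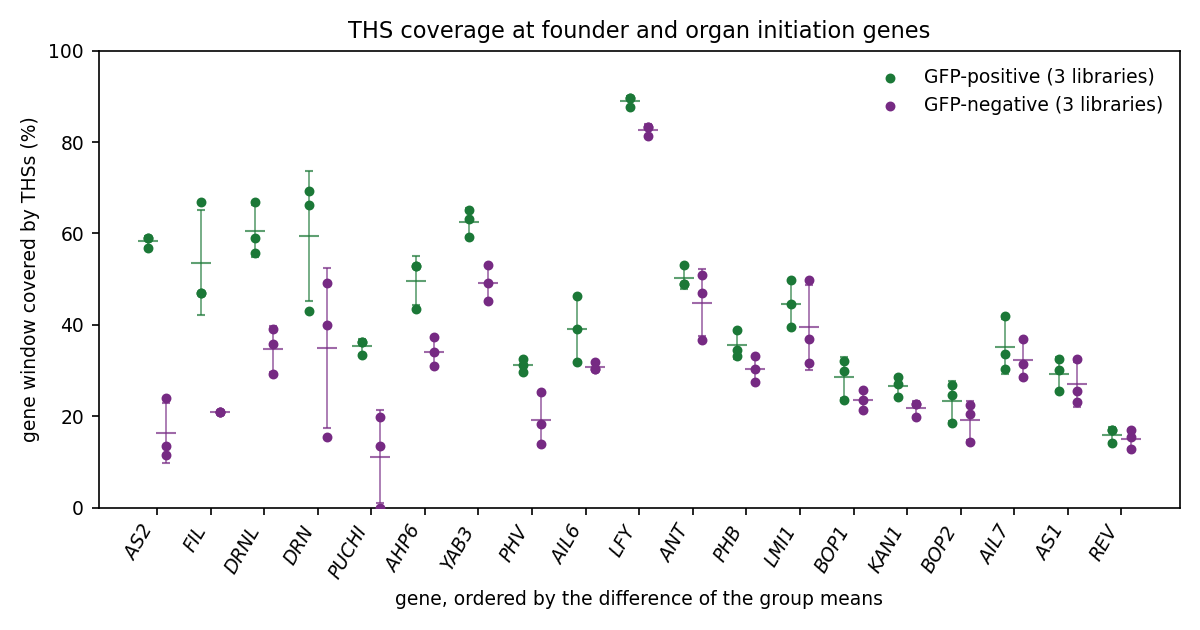
Share of each gene window covered by THSs (y axis, percent) at the 19 founder and organ initiation genes (x axis); points are the 3 libraries of each population, some of them overlapping, and bars are the mean ± SD. The group means differ by 42.0 percentage points at AS2 and by 0.924 at REV, the smallest difference of the list.

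Organ boundary, floral and epidermal genes also had higher coverage in founder cells by camera, though no member passed over all genes. With an estimated correlation these calls were lost, with an adjusted p of 0.199 for boundary, 0.585 for floral and 0.199 for epidermal genes. Boundary genes (11 tested) had 40.8% ± 1.96 against 36.4% ± 1.16 (limma's camera, n = 3 each, adjusted p = 0.0209, and adjusted p = 0.199 with an estimated correlation), and none rose or fell when adjusted over the list alone. CUC2 had 39.0% ± 1.39 against 27.0% ± 5.01 and CUC3 63.2% ± 4.91 against 55.3% ± 2.36. Flowering and floral identity genes (25 tested) had 30.4% ± 2.09 against 26.4% ± 1.79 (limma's camera, n = 3 each, adjusted p = 0.0183, and adjusted p = 0.585 with an estimated correlation). When adjusted over the list alone, AP1, CAL and the floral homeotic gene AG (19.7% ± 0.751 against 16.9% ± 0.652) rose and the flowering signal gene FT fell. FT had no listed THS in founder cells and 3.58% ± 1.25 in GFP-negative libraries. SOC1, SVP, AGL24 and FLC, which time flowering, did not pass.

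Epidermal genes (11 tested) had 27.9% ± 1.6 against 23.7% ± 1.15 (limma's camera, n = 3 each, adjusted p = 0.0034, and adjusted p = 0.199 with an estimated correlation). When adjusted over the list alone, FDH and GL1 rose. GL1, which starts leaf hairs, had 29.1% ± 0.166 against 15.7% ± 4.54. By limma's fry in 1 direction the adjusted p was 0.0435 for boundary, 0.0542 for epidermal and 0.242 for floral genes. In flanks alone the adjusted p was 0.369 for boundary and 0.206 for floral genes (camera). The boundary call was also lost without GFP-positive replicate 1 (adjusted p = 0.112, camera), GFP-positive replicate 3 (adjusted p = 0.0518) or GFP-negative replicate 3 (adjusted p = 0.0757), and the floral call without GFP-positive replicate 1 (adjusted p = 0.102) or GFP-negative replicate 1 (adjusted p = 0.1).

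Photosynthesis genes (20 tested) had 30.1% ± 3.36 in founder cells and 33.1% ± 0.526 in their neighbours (limma's camera, n = 3 each, adjusted p = 0.0362, and adjusted p = 0.585 with an estimated correlation). By limma's fry in 1 direction the list's adjusted p was 0.278, and by camera with a replicate block it was 0.147. LHCB1.2, a light-harvesting protein gene, had no listed THS in founder cells and 8.27% ± 1.79 in their neighbours (limma adjusted p = 0.0371), and it fell together with RBCS3B when adjusted over the list alone. The list's adjusted p was 0.102 without GFP-positive replicate 1, 0.233 without GFP-positive replicate 3 and 0.248 without GFP-negative replicate 1 (camera). LHCB1.2 passed limma without GFP-negative replicate 3 but not without any other library, where its adjusted p lay between 0.079 and 0.13. For vascular genes no difference passed by camera: the 12 tested had 24.6% ± 2.67 and 29.5% ± 1.05 (limma's camera, n = 3 each, adjusted p = 0.209), with a median change of -1.1 points. SEOR1 (AT3G01680), a phloem sieve element protein gene, fell from 19.7% ± 1.77 to 1.33% ± 1.16 (limma adjusted p = 0.00626) and was the only vascular gene that changed over all genes or over the list alone.

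The meristem and hormone lists did not pass camera in either direction, but the auxin list passed a test for changes in either direction. Shoot meristem genes (17 tested) had 36.1% ± 3.07 and 34.5% ± 2.03 (limma's camera, n = 3 each, adjusted p = 0.505), and no member passed by either count. The stem cell genes WUS and CLV3 had 21.1% ± 2.93 against 23.7% ± 1.46 and 15.3% ± 13.4 against 16.5% ± 2.08, while ATH1, a BELL-type homeobox gene, had 41.7% ± 2.79 against 23.1% ± 6.9. Auxin genes (37 tested) had 32.4% ± 2.55 and 32.3% ± 1.54 (limma's camera, adjusted p = 0.7), with a mean change of 0.0575 and a median of -0.529 points. Within this list groups did not overlap at 4 genes covered more in founder cells, among them YUC4 at 55.1% ± 9.2 against 28.5% ± 9.92, and at 6 covered less, among them the efflux carrier gene PIN7 at 14.8% ± 3.3 against 38.7% ± 6.6 and IAA1 at 9.87% against 23.2% ± 5.75. None of the 37 passed over all genes or over the list alone. The mixed test of limma's fry, for members that change in either direction, gave an adjusted p of 3.2e-08 for auxin genes, the smallest of the 13 lists, 0.69 for meristem and 0.559 for cytokinin genes. It passed for 6 lists, and with shuffled values for up to 3 lists, at least 1 in 14 of 20 shuffles.

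Cytokinin genes (19 tested) had 30.9% ± 3.72 and 32.0% ± 3.87 (limma's camera, n = 3 each, adjusted p = 0.609), and none passed. Cell cycle genes (14 tested) had 20.0% ± 1.56 and 18.5% ± 1.49 (limma's camera, n = 3 each, adjusted p = 0.0837). Genes of stress and protoplasting (15 tested) were widely accessible in both populations, at 62.4% ± 2.79 and 61.4% ± 1.82 (limma's camera, n = 3 each, adjusted p = 0.236). Housekeeping genes, a control for open chromatin, had 30.2% ± 2.48 and 32.0% ± 0.934 (9 tested, adjusted p = 0.535, limma's camera). Seed storage and seed fate genes, a control for closed chromatin, had 14.8% ± 0.635 and 14.6% ± 0.448 (9 tested, adjusted p = 0.611, limma's camera).

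**Figure D4:**
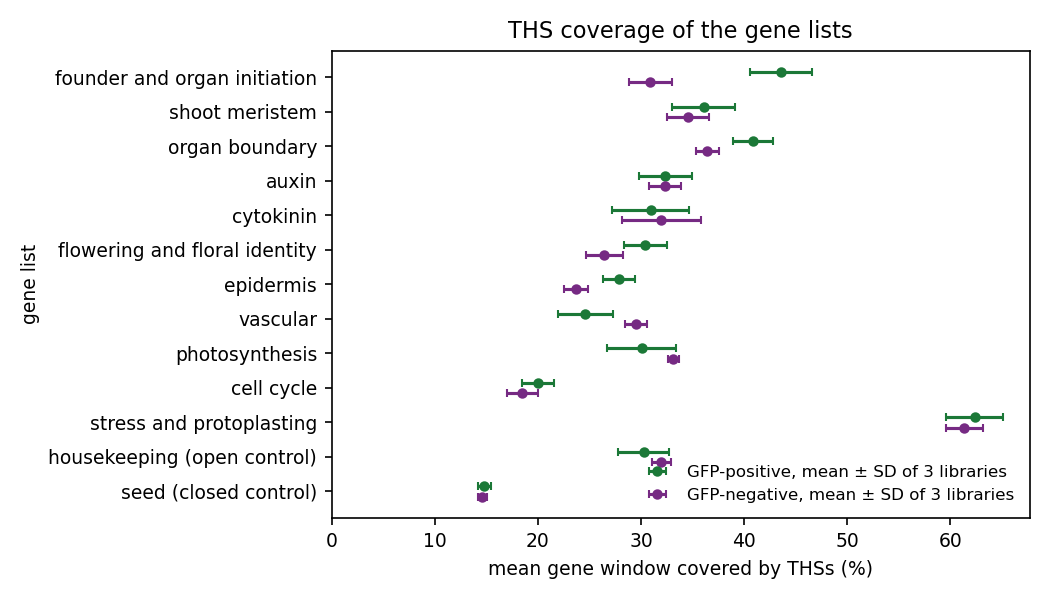
Mean share of the gene windows covered by THSs (x axis, percent) for each of the 13 gene lists (y axis) in GFP-positive and GFP-negative libraries; points are the mean and bars the SD of 3 libraries. The founder and organ initiation list has the largest difference, 43.6% against 30.9%.

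The authors' deposited table named 121 genes with a dTHS-up site and 392 genes with a dTHS-down site, with no values. Its header does not state which population is the reference. Coverage gave the direction. At the 113 protein-coding dTHS-up genes of the authors' deposited table, mean coverage was 42.7% ± 2.87 in GFP-positive and 33.0% ± 1.84 in GFP-negative libraries (SD, n = 3 each; exact permutation p = 0.1). At the 375 protein-coding dTHS-down genes it was 19.8% ± 2.32 and 32.9% ± 1.88 (SD, n = 3 each; exact permutation p = 0.1). Groups did not overlap, in the direction of the list, at 56 of the 113 and 268 of the 375 genes. Chance gives at most 10% for both directions together. The genes were chosen by the authors on these samples, so these counts are not independent evidence of the direction.

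Founder genes were frequent among the dTHS-up genes of the authors' deposited table. It listed 8 of the 19 founder and organ initiation genes, DRNL, PUCHI, FIL, YAB3, AS2, BOP1, PHV and AHP6, where 0.0878 were expected (Fisher's exact test, two-sided, over 26176 genes of the table; adjusted p = 3.1e-13 over 26 tests), and no founder gene as dTHS-down. The 8 genes include DRNL, whose promoter defined the sorted cells, and the test was not repeated without it. No other list passed. The tests of the lists against these columns were not in the plan fixed beforehand. The table gave ATH1, ARF5, CAL and SEP4 as dTHS-up. It gave PIN7, YUC6 and IAA1 of the auxin list (adjusted p = 0.134), SEOR1 and CLE44 of the vascular list (adjusted p = 0.134), ARR15, FUL and RBCS3B as dTHS-down. Boundary, epidermal, cell cycle, stress, housekeeping and seed genes were in neither column.

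Of the genes called from coverage, 8 of the 76 higher genes were dTHS-up and 68 of the 249 lower genes were dTHS-down in the authors' deposited table. The direction of these columns was read from the same libraries, and the overlap was not tested, so these counts are not independent evidence.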

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

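The tests on the distance and length of the deposited gene lists, on gene lengths, tRNA order and the reach of the name search in the wide site, and on the balance of group-only regions were chosen after the result was seen.

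A single THS carried 15.8% of all site scores on average (13.9% to 17.3% per library). It lay on chromosome 2 from 3259601 to 3509800, 250200 bp wide with the same ends in all 6 libraries. The main comparisons included it, and without it limma called 340 genes where it had called 325. Reads from copies of mitochondrial genes are a candidate source: 5 of 85 protein-coding genes inside had exactly the length of a mitochondrial gene, against 224 of 27359 elsewhere (Fisher's exact p = 0.000739), and 5 tRNA genes in a row followed the mitochondrial order (permutation p = 0.0065, 10000 shuffles). A test for mitochondrial names gave a Fisher's exact p of 1, but its search found 0 of the 284 genes of the mitochondrial genome itself and 1 of the 171 genes inside has a symbol of its own, so it could not have found copies. The share of scores differed by 0.404 percentage points between overlapping groups, which argues against a difference between founder cells and their neighbours. Whether organelle reads were removed before site calling is not given in the sources used here, so the origin of the reads stays open.

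The authors' deposited table lists 25995 genes with THSs in GFP-positive and 21098 in GFP-negative cells, while the GFP-positive libraries have no more sites. Different distance limits are a candidate explanation, since the GFP-positive list was best matched by genes with a THS within 5000 bp in all 3 libraries (Jaccard index 0.975) and the GFP-negative list by 1000 bp (Jaccard index 0.97). At a common 1000 bp the GFP-positive libraries had 20094 such genes and the GFP-negative libraries 20417, a difference of -323, which argues against more genes near a site in founder cells. The rule the authors used is not given in the sources used here.

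The GFP-negative libraries alone shared 562 regions and the GFP-positive libraries alone 112, a ratio of 5.02. Unequal numbers of called sites may account for much of this, since the ratio was 1.38 with the same number of top-scoring sites per library. Settings that do not equalise the numbers gave 2.53 (sites of at least 400 bp), 3.81 (at least 2 of 3 libraries), 3.92 (50 percent covered) and 6.65 (gaps of 200 bp merged). Leaving out each library gave ratios from 1.75 (without GFP-negative replicate 3) to 7.31 (without GFP-negative replicate 1), with 2.34 without GFP-positive replicate 1. A difference between founder cells and their neighbours cannot be told apart from it: the numbers of sites overlapped between the groups (exact permutation p = 0.2), and read depth is unknown.

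The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. As many regions of the GFP-positive libraries alone came from 3 of the 10 splits (real value 112, highest other 231), and as many of the GFP-negative libraries alone from 1, the real one (562, highest other 231). For genes with different coverage it was 1 (325, highest other 50), and for gene lists 1 (5, highest other 3).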

How the results depend on the processing

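The settings with the same number of top-scoring sites per library, with all nuclear genes and without the site over 200 kb were chosen after the result was seen. Of 867 alternative values, 751 kept direction and side of the threshold or, for counts, stayed within 1.5 times. For 35 named genes, 469 of 523 did, 39 no longer passed, 11 newly passed and 4 reversed. For lists, 157 of 182 did, 19 no longer passed, 1 newly passed and 5 reversed, none of these past the threshold. Where values changed, the cause was not tested.

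Regions of the GFP-positive libraries alone (112) numbered 173 with at least 50 percent covered, 63 merged over 200 bp gaps, 327 in at least 2 of 3, and 305 with equal numbers of top-scoring sites. Leaving out each library gave 135 to 354. Regions of the GFP-negative libraries alone (562) numbered 1246 in at least 2 of 3, and 609 to 1052 leaving out each library. Without merging, 193.7 kb and 413.3 kb were specific to each.

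The covered length differed by -1.17 to 0.0314 Mb leaving out each library. Share differences ran from -0.587 to 0.0702 points for gene bodies, -0.0434 to 0.0393 for other genes and -0.0704 to 0.0671 outside. With 2000 bp flanks the latter pair gave 0.00695 and -0.0152, and midpoints gave -0.476 outside.

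Genes with different coverage (325) numbered 30 with a replicate block, 28 of them shared (1 higher, 29 lower), and 254 to 540 leaving out each library. Higher genes (76) numbered 125 in flanks alone, 119 among all nuclear genes, 187 with equal numbers, and 84 to 208 leaving out each library. Lower genes (249) ran from 141 to 443. Differences reversed to -0.111 at AT4G35485 (2000 bp flanks), to 3.9 (equal numbers) and 0.411 (library mean) at RAX2, and at ARR4 ranged from -13.7 to 2.49 leaving out each library.

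Lists called (5) numbered 3 in flanks alone, 0 with an estimated correlation, 2 by fry (founder and boundary), and 2 to 6 leaving out each library: 2 without GFP-positive replicate 1, and 3 without GFP-positive replicate 3 or GFP-negative replicate 1. The founder list's adjusted p was 0.199 with an estimated correlation, and 7.3e-09 to 6.31e-08 leaving out each library.

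The direction by camera turned to higher in founder cells for auxin genes in flanks alone (adjusted p = 0.768), divided by the library mean (0.788) and without GFP-negative replicate 2 (0.865), for housekeeping genes in flanks alone (0.768), and for cytokinin genes without GFP-positive replicate 1 (0.971). Leaving out each library, the adjusted p ran from 0.322 to 0.971 for auxin and from 0.233 to 0.971 for cytokinin genes. The block gave photosynthesis genes an adjusted p of 0.147. Deviations of same-numbered libraries correlated at 0.16, 0.0672 and 0.0389. GFP-positive replicate 2 correlated best with GFP-negative replicate 3 (0.0853). The other pairs with different numbers had negative correlations, down to -0.145. No label says that a number marks a shared sort, so the main fit used no block. These correlations lean towards a pairing but are too few and too weak to show or exclude one.

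The similarity difference kept its direction (0.0313 to 0.041), as did dTHS-up (8.05 to 10.8 points) and dTHS-down coverage (-14.4 to -12.4). Not run were all sequences against nuclear ones (the lists hold nuclear chromosomes alone), motif settings (no genome) and count, threshold, overlap and pseudocount settings of the authors' deposited table (no values or positions). Depth is unknown, so an unlisted site is not shown to be closed.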

Other observations

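The family and gene tests of this part were chosen after the result was seen. The authors' deposited table also holds families outside the lists chosen beforehand. Its genes were chosen by the authors on these samples, so their coverage is not independent evidence. Of 8 SHI-related (SRS) genes, which activate auxin synthesis in young organs, 3 were dTHS-up. This was the only one of 625 families named by symbol that passed (1250 one-sided Fisher's exact tests, adjusted p = 0.00663). The 3 genes had higher mean coverage in founder cells in these libraries: SRS7 had 59.8% ± 6.05 against 23.2% ± 14.5, STY1 38.3% ± 8.21 against 13.4% ± 7.01 and STY2 29.3% ± 8.56 against 11.4% ± 3.73 (SD, n = 3 each). None of them passed limma over all genes (adjusted p 0.196, 0.196 and 0.273). Of the 6 YABBY genes, 4 were dTHS-up in the authors' deposited table; the family was picked because its members had been seen there, so no test is given. Besides FIL and YAB3, which the founder list holds, these were YAB2 with 35.3% ± 10.9 against 8.72% ± 8.64 and YAB5 with 31.8% ± 6.32 against 11.4% ± 4.53.

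A few other dTHS-up genes of the authors' deposited table were picked after their values had been seen. CYP78A5, which promotes organ growth, had a coverage of 38.9% ± 5.72 in founder cells and 13.0% ± 4.64 in their neighbours, and KNATM, a KNOX gene without a homeodomain, 45.1% ± 5.18 and 18.8% ± 9.06. The gibberellin-inactivating oxidase gene GA2OX4 had 78.8% ± 5.95 and 54.8% ± 6.87 (SD, n = 3 each throughout). BLH4, a BELL-type homeobox gene, rose from 20.0% ± 1.52 to 30.1% ± 1.31 (limma adjusted p = 0.0367). One dTHS-up gene, HLS1, went the other way, with 49.0% ± 2.08 in founder cells and 59.7% ± 6.11 in their neighbours.

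Among the dTHS-down genes of the authors' deposited table, coverage fell in founder cells at CYP707A2, an abscisic acid hydroxylase gene (14.5% ± 1.45 against 42.2% ± 1.67, limma adjusted p = 0.00217). LOG8, a cytokinin-activating enzyme gene, fell from 32.5% ± 1.19 to 8.92% ± 3.15 (limma adjusted p = 0.0114), and UNE10, a bHLH gene related to the phytochrome-interacting factors, from 75.9% ± 3.36 to 49.5% ± 1.27 (limma adjusted p = 0.0104).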
